A study of Rattus norvegicus with 12 samples.

How the data were processed

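Expression in rat lung was measured on 12 one-colour Affymetrix RG-U34A arrays, 3 in each of 4 groups. Per the labels, the authors made the values with RMA (background correction, normalization between arrays and summary over the probes of a set), in units of intensity; the version of RMA was not given. All values are above 0 and on a linear scale, so log2 of each value was used, with no further scaling. Array medians lay between 647 and 677 intensity units. The number of arrays limits the precision.

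Probe sets were given gene symbols from the annotation table of the array's platform. Of 8799 probe sets, 59 array controls were left out and 8740 were tested. Of these, 7006 carried 1 gene symbol, 308 several and 1426 none. Tests of gene lists used 4736 genes with 1 symbol, each represented by the probe set with the highest mean over the 12 arrays.

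Every pair of arrays was compared before the tests. In each group, 1 pair of arrays differed far less than any other pair, with a robust SD of the log2 differences under 0.1: T/SS replicates 2 and 3, and replicates 1 and 3 of T/HS, T/SS-LDL and T/HS-LDL. The arrays of such a pair were averaged, which left 8 samples, 2 per group. This choice was made after the data were examined: the plan fixed before had all 12 arrays as separate samples, and results of that plan are given beside those of the 8 samples. The labels call each array a biological replicate.

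One model with the 4 groups was fitted to the 8 samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 4 residual degrees of freedom, 2.85 prior degrees of freedom and a prior SD of 0.131 on the log2 scale. Contrasts were T/HS against T/SS, T/HS against T/HS-LDL, T/HS-LDL against T/SS-LDL, T/SS-LDL against T/SS, and the interaction, which is the shock effect without ligation minus that with ligation. A further contrast, shock over both ligation states, is the mean of both shock effects and was chosen after the data were examined. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 8740 probe sets, and the threshold was an adjusted p of 0.05. Errors of genes are standard errors from limma.

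Of 35 gene lists fixed before the data were examined, 33 had at least 5 measured genes; the lists of B cells and plasma cells and of lymph node and thymus did not. The 33 lists were cytokines and chemokines, NF-kB targets and adhesion molecules, immediate early genes, hypoxia and glycolysis, heat shock and protein folding, oxidative stress response, glucocorticoid responsive genes, interferon responsive genes, coagulation and fibrinolysis, extracellular matrix and remodelling, vascular tone and vasoactive peptides, p53 with growth arrest and apoptosis, cell cycle, circadian clock, polyamine and arginine metabolism, mitochondrial respiratory chain, ribosomal proteins, epithelial ion and water transport, xenobiotic metabolism P450, circulating acute phase and liver-type genes, alveolar type II cells, alveolar type I cells, airway club and ciliated cells, endothelium, neutrophils, monocytes and macrophages, mast cells, T and NK cells, erythroid cells and platelets, smooth muscle and pericytes, fibroblasts, heart muscle of pulmonary veins, and adipose and pleural mesothelium. Each was tested with limma's camera, which asks whether the genes of a list rank higher or lower than the other genes, with a preset correlation of 0.01 between genes and adjustment over the 33 lists within a comparison. Camera was also run with the correlation estimated from the data. Its p-values then rest on the 4 residual degrees of freedom, where the preset correlation lets them rest on the number of genes. Fry, which asks whether the genes of a list move on balance one way, was run as well. A list's mean is the mean log2 fold change of its genes, with the standard error over genes. A sample's score for a list is the mean log2 difference of its genes from the T/SS mean. Cell type lists hold marker genes and do not identify cells.

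Genes were chosen for naming by a rule fixed before the data were examined: for each comparison, up to 12 genes higher and 12 lower with the largest change among those past the threshold with groups that do not overlap (8 and 8, by adjusted p alone, for the interaction); of each list, up to 4 genes past the threshold and up to 2 with the highest mean that did not pass; and, where fewer than 10 genes passed, the 10 with the smallest p. A gene named for 1 comparison may be given in the others. Other genes are named as chosen after their values were seen.

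The replicate numbers were checked for pairing: across groups, deviations of same-numbered arrays from their group means correlated above 0.1 in 3 of 18 pairs, with r from -0.166 to 0.189. With near-identical arrays in each group these 18 values are not independent, so the check cannot settle pairing. No pairing was used, since nothing in the labels says that the numbers mark a shared day. The planned replicate block could be run only with the 12 arrays, since averaged samples no longer carry 1 number. Alternatives tried were shifting arrays to a common median, quantile normalization, only probe sets above the median of mean value, gene means, an offset of 16, array weights, eBayes with trend and robust, the compared groups alone, an adjusted p of 0.10, a 1.5-fold minimum, an unadjusted p of 0.01, leaving out each sample, and for lists also the mean of a gene's probe sets, estimated correlation and fry. The planned fit to 12 separate arrays and its planned replicate block are given as alternatives to the 8 samples. Alternatives added after the data were examined were the 12 arrays with the sample as a random block (duplicateCorrelation, consensus correlation 0.961), an exact permutation test of list scores, and lists without Il1b or without Cxcl10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

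The procedure was tested on simulated data with the spread of the 8 samples. With 200 of 8740 probe sets changed in T/HS against T/SS, it recovered 0% of them at 1.5-fold, 71.2% at 2-fold, 95.55% at 4-fold and 98.3% at 8-fold, with 8.9, 12.4 and 12.6 false calls per run at the 3 larger sizes (10 simulations each). These variances were drawn from each gene's posterior. An earlier version with shrunken variances, replaced after its output was seen since it understates their spread, gave 0%, 86.2%, 97.85% and 99.1%. In both, genes were independent and 200 probe sets changed by 1 size, which makes the adjusted threshold easier to pass. In the data, 121 probe sets differed over 2-fold in T/HS against T/SS and 0 passed, so 0 calls do not show that such changes are absent. With no probe set changed, the 8 samples gave a median of 0 false calls in every comparison (at most 1 in 20 simulations). With each near-identical pair treated as separate samples, the median was 294 to 340 false calls, depending on the comparison. For the interaction it was 314.5, above the 1 call of the 12 real arrays, so this simulation does not measure false calls for these arrays. In simulations with genes independent of each other, camera called a mean of 0.1 of 33 lists on unchanged data, and called the neutrophil list, shifted by 0.5, in 100% of 20 simulations.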

Results

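Gene expression in rat lung was measured on 12 arrays, 3 from each of 4 groups of male Sprague-Dawley rats. T/SS rats (trauma and sham shock) had a laparotomy and a sham-shock period of 90 min. T/HS rats (trauma and hemorrhagic shock) had a laparotomy and 90 min of shock at 30 mmHg, which left them with lung injury. T/SS-LDL and T/HS-LDL rats were treated likewise but with the lymph duct tied off, and neither group had lung injury. Lungs were taken 3 h after the period ended, 4.5 h after shock began. Array medians lay between 647 and 677 intensity units, and between 26 and 54 probe sets per array lay within 2% of the array's highest value. Sftpc, a surfactant protein, Hbb, a globin, and Rps29, a ribosomal protein, shared these highest values (log2 fold change of -0.01 each for T/HS against T/SS), and no change could be measured there.

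In each group, 1 pair of arrays was near-identical. The robust SD of the log2 differences was 0.00993 to 0.0548 in these 4 pairs, against 0.164 to 0.232 in the other 8 pairs within groups and 0.172 to 0.294 in the 54 pairs between groups. No probe set differed over 2-fold in a near-identical pair, against 40 to 256 in the other pairs of a group. Pearson's r across probe sets was 0.9994 to 0.9999 in these pairs and at most 0.994 in the others. Each near-identical pair was averaged to 1 sample, so the comparisons rest on 8 samples, 2 per group. On simulated unchanged data, treating such pairs as separate samples gave a median of 322 false calls for T/HS against T/SS (255 to 355 in 20 simulations), against 0 (at most 1) with 8 samples. The 12 real arrays gave 629 calls there, but only 1 for the interaction, against 247 to 376 simulated. For T/HS-LDL against T/SS-LDL they gave 127, against 237 to 361, and for T/SS-LDL against T/SS 141, against 219 to 342. The real counts of these contrasts lay below the simulated range. The simulation, with genes drawn independently, thus does not measure false calls for these arrays.

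**Figure D1:**
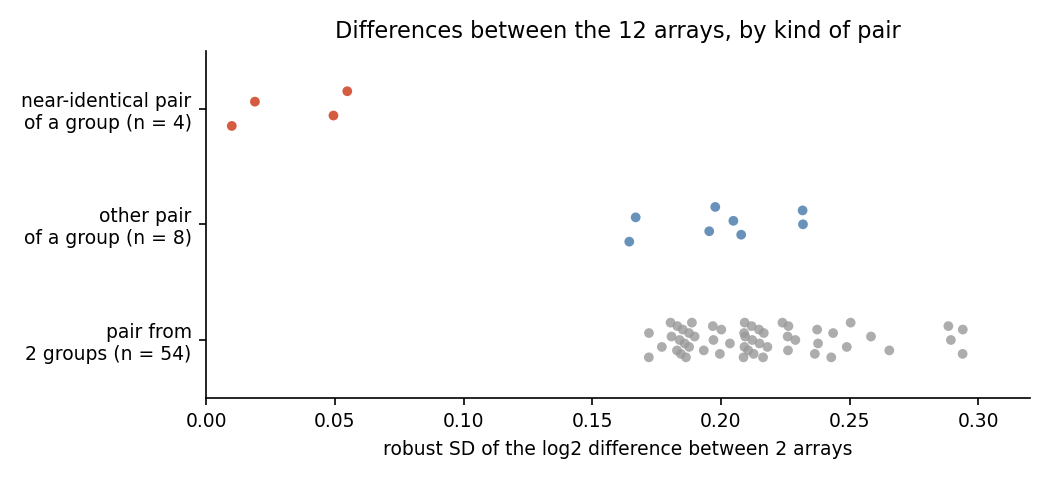
Robust SD of the log2 differences between 2 arrays (x axis, log2 units), 1 point per pair, for near-identical pairs of a group (n = 4), other pairs of a group (n = 8) and pairs from 2 groups (n = 54). The near-identical pairs lie at or below 0.0548 and all other pairs at or above 0.164.

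T/HS was compared with T/SS to find transcripts that differ with shock and lung injury together. Il1b, which encodes the cytokine interleukin 1 beta, was higher in T/HS by 2.90 ± 0.38 on the log2 scale (SE, n = 2 samples per group, limma adjusted p 0.305). Ccr2, a receptor that draws monocytes into tissue, was higher by 0.65 ± 0.09 (limma adjusted p 0.305), and Mapk12, a stress-activated kinase, differed by -0.89 ± 0.11 (limma adjusted p 0.305). Among the 13 measured genes of the neutrophil list, all were higher in T/HS, with a mean log2 fold change of 0.88 ± 0.23 (SE over genes) and a camera adjusted p of 4.3e-08. With the correlation between genes estimated from the data, the neutrophil list's adjusted p was 0.394.

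None of the genes with the smallest p passed the threshold. In both T/HS samples Ndufc1, a subunit of respiratory complex I (-0.92 ± 0.15), Canx, a chaperone of the endoplasmic reticulum (-1.06 ± 0.18), Maob, a monoamine oxidase (-1.09 ± 0.20), Tfpi, an inhibitor of coagulation (-0.85 ± 0.15), Abcc3, an export pump (-0.77 ± 0.13), Cryab, a small heat shock protein (-0.61 ± 0.11), and the uncharacterised C8h15orf61 (-0.58 ± 0.09) lay below both T/SS samples, each with a limma adjusted p of 0.373. Limma called 0 of 8740 probe sets at an adjusted p of 0.05 and 0 at 0.10, with 769 at an unadjusted p under 0.05 (437 expected by chance) and 200 under 0.01 (75 higher, 125 lower; 87.4 expected). Over 2-fold differences were seen in 121 probe sets, 87 higher and 34 lower. With the 12 arrays as separate samples, 629 passed (246 higher, 383 lower), 456 with the replicate block, and 25 with the sample as a random block. Counts with a T/HS sample left out rest on a lone T/HS sample, whose spread is taken from the other groups. The difference between the T/HS samples then no longer enters the spread. Without the averaged T/HS sample (replicates 1 and 3), 139 passed (120 higher, 19 lower), and without T/HS replicate 2, 5 passed.

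Interferon responsive genes were higher in T/HS by a mean of 1.51 ± 0.26 (16 of 17 genes, camera adjusted p 4.3e-08; 0.559 with estimated correlation). This mean rests on 1 sample: the interferon score was 2.68 in T/HS replicate 2 and 0.34 in the averaged T/HS sample, against -0.06 to 0.06 in T/SS, and without T/HS replicate 2 the list's mean was 0.34 with a camera adjusted p of 0.000995. B2m and RT1-A, the probe sets of the list with the highest signal, which encode parts of MHC class I, differed by 0.05 ± 0.10 and 0.08 ± 0.09. Cxcl10, a chemokine induced by interferon and chosen after its values were seen, was higher by 3.99 ± 1.84 (limma adjusted p 0.582). S100a9 and Lcn2, the neutrophil probe sets with the highest signal, which encode a calcium-binding and an iron-scavenging protein, were higher by 1.21 ± 0.39 and 0.92 ± 0.44 (limma adjusted p 0.482 and 0.595). In 10 of the 13 neutrophil genes both T/HS samples lay above both T/SS samples. By chance this holds for 16.7% in a given direction for 1 gene. Genes that vary together would lie apart together, so the 13 are not independent trials and this count does not exclude chance. The neutrophil call was kept with each sample left out in turn, with means from 0.65 to 1.12 and adjusted p up to 9.83e-05.

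Camera called 4 further lists, none of them with estimated correlation. Cytokines and chemokines were higher by a mean of 0.53 ± 0.23 (adjusted p 0.00952, 0.559 with estimated correlation) and circulating acute phase genes by 0.31 ± 0.11 (adjusted p 0.012, 0.461 with estimated correlation). Without T/HS replicate 2 both calls were lost, with means of 0.15 and adjusted p of 0.115 and 0.332. Both were also lost with the planned 12 separate arrays, at means of 0.40 and 0.24 (adjusted p 0.0568, and 0.0588 with the replicate block). Heat shock and protein folding genes were lower, with a mean of -0.21 ± 0.08 (adjusted p 0.00952, 0.559 with estimated correlation), a call lost without T/SS replicate 1 (mean -0.15, adjusted p 0.0628) or without the averaged T/HS sample, where the mean stayed at -0.20 (adjusted p 0.15). Heart muscle genes, transcribed in the sleeves of the pulmonary veins, were higher by 0.33 ± 0.10 (adjusted p 0.0367, 0.609 with estimated correlation). That call was lost without the averaged T/SS sample, with a mean of 0.046 (adjusted p 0.559), and at means of 0.26 without the averaged T/HS sample (adjusted p 0.196) and 0.41 without T/HS replicate 2 (adjusted p 0.107). Among the probe sets with the highest signal were Hsp90ab1, a chaperone (-0.25 ± 0.13), Hspb1, a small heat shock protein (-0.36 ± 0.22), and Atp2a2, a calcium pump of heart muscle (0.18 ± 0.22). Adjusted over the list alone, 22 members in 11 lists passed, 7 of them in the neutrophil list, and 0 passed over all probe sets.

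The other 27 lists did not pass in T/HS against T/SS, with means from -0.24 (xenobiotic metabolism P450) to 0.40 (NF-kB targets) and a smallest adjusted p of 0.0570. Among lists that passed in none of the comparisons, the mean in T/HS against T/SS was 0.17 for hypoxia and glycolysis, 0.14 for glucocorticoid responsive genes, 0.13 for the circadian clock, 0.11 for extracellular matrix, 0.10 for p53 and apoptosis, 0.04 for polyamine metabolism and 0.02 for alveolar type II cells. It was -0.01 for fibroblasts, -0.05 for ribosomal proteins, -0.06 for endothelium, -0.07 for the cell cycle, -0.08 for epithelial ion transport, -0.10 for both coagulation and vascular tone, -0.13 for erythroid cells and platelets, -0.18 for adipose and mesothelium and -0.24 for alveolar type I cells. The mean and camera's direction differed in sign for fibroblasts and for epithelial ion transport, and in none of the called lists. No list call held with estimated correlation in any comparison. How many lists camera would call by chance in comparisons of 2 against 2 samples was not counted on these samples; in the 35 splits of the 8 samples into 4 and 4, a different comparison and fit, it called a median of 6.

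**Figure D2:**
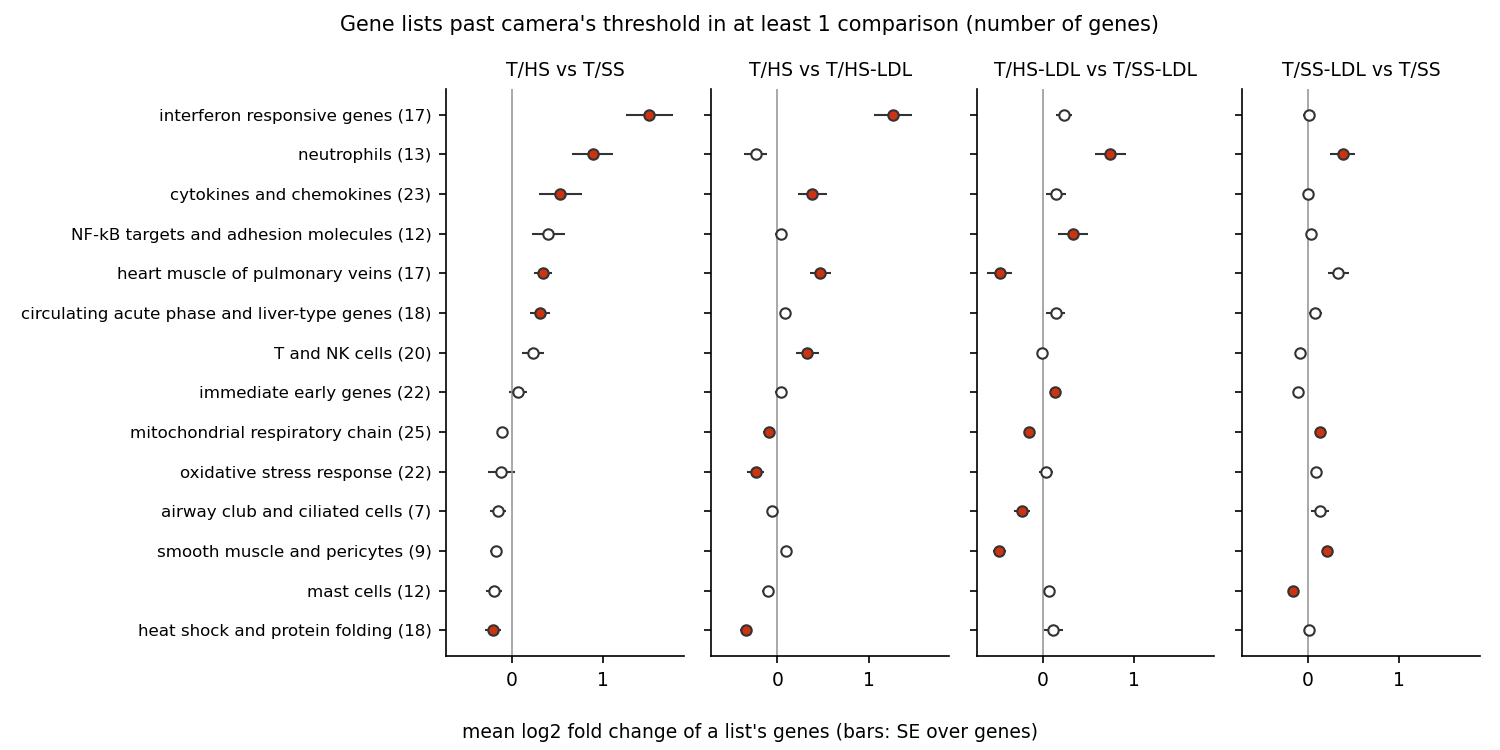
Mean log2 fold change (x axis) of the genes of each list past camera's threshold in at least 1 comparison, with bars for the SE over genes, the number of genes in brackets and filled points where camera's adjusted p was under 0.05. Neutrophil genes averaged 0.88 in T/HS against T/SS and 0.74 in T/HS-LDL against T/SS-LDL.

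T/HS was compared with T/HS-LDL, both shocked, to find transcripts that differ with lung injury. These groups also differ by ligation, so this comparison cannot tell lung injury from ligation itself. Mapk12 was lower in T/HS, with a log2 difference of -0.79 ± 0.11 (SE, n = 2 samples per group, limma adjusted p 0.677), as it was against T/SS. Canx differed by -1.10 ± 0.18, Ivns1abp, a protein that binds a viral protein and actin, by -0.75 ± 0.12, Zfp706, a zinc finger protein, by -0.83 ± 0.14, and Cyb5a, an electron carrier, by -0.99 ± 0.19, each with a limma adjusted p of 0.677. Neutrophil genes were not higher in T/HS than in T/HS-LDL: the mean was -0.24 ± 0.12 (camera adjusted p 0.210), and S100a9 differed by -0.60 ± 0.39. Interferon responsive genes were higher by a mean of 1.27 ± 0.21 (17 of 17 genes, camera adjusted p 1.37e-06, 0.655 with estimated correlation), but without T/HS replicate 2 the mean was 0.10 with an adjusted p of 0.655.

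Sult2a6, a sulfotransferase (-0.63 ± 0.11), Marchf8, a ubiquitin ligase (-0.67 ± 0.12), Pawr, a regulator of apoptosis (-0.55 ± 0.10), Ndufc1 (-0.78 ± 0.15) and C8h15orf61 (-0.51 ± 0.09) were also lower in both T/HS samples, each with a limma adjusted p of 0.677. Lpl, which encodes lipoprotein lipase, differed by -1.36 ± 0.26 (limma adjusted p 0.677) and Klf9, a transcription factor induced by glucocorticoids, by -0.67 ± 0.15 (limma adjusted p 0.710). Cat, which encodes catalase and was chosen after its values were seen, differed by -2.04 ± 0.45 from T/HS-LDL and by -2.42 ± 0.45 from T/SS (limma adjusted p 0.710 and 0.373). Limma called 0 probe sets at an adjusted p of 0.05, with 557 at an unadjusted p under 0.05 and 106 under 0.01 (14 higher, 92 lower). With the 12 arrays as separate samples 372 passed, 130 with the replicate block and 0 with the sample as a random block. Simulated unchanged data gave a median of 340 for the separate arrays, which does not measure false calls for these arrays. Counts with a T/HS sample left out rest on a lone T/HS sample, whose spread is taken from the other groups. Without the averaged T/HS sample 66 passed (63 higher, 3 lower), and without T/HS replicate 2, 4 passed.

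Heat shock and protein folding genes were lower in T/HS than in T/HS-LDL in 17 of 18 genes, with a mean of -0.34 ± 0.07 (camera adjusted p 2.61e-05, 0.655 with estimated correlation). Without the averaged T/HS-LDL sample (replicates 1 and 3) their mean was -0.13 with an adjusted p of 0.332. Oxidative stress genes had a mean of -0.24 ± 0.09 (adjusted p 0.000509, 0.364 with estimated correlation) and -0.08 without the averaged T/HS sample (adjusted p 0.426). Heart muscle genes were higher by 0.47 ± 0.11 (adjusted p 0.000509, 0.655 with estimated correlation), and by 0.073 without T/HS-LDL replicate 2 (adjusted p 0.549). T and NK cell genes were higher by 0.33 ± 0.13 (adjusted p 0.00176, 0.655 with estimated correlation), lost without the averaged T/HS sample (mean 0.13, adjusted p 0.120) or the averaged T/HS-LDL sample (mean 0.21, adjusted p 0.288). The calls of cytokines and chemokines (0.38 ± 0.16, adjusted p 0.0159) and of the mitochondrial respiratory chain (-0.10 ± 0.06, adjusted p 0.0215), both 0.655 by adjusted p with estimated correlation, were also lost. The first had a mean of 0.0051 without T/HS replicate 2 (adjusted p 0.903) and of 0.34 without the averaged T/HS-LDL sample (adjusted p 0.243), the second a mean of -0.086 without the averaged T/HS sample (adjusted p 0.138) and of 0.023 without T/HS-LDL replicate 2 (adjusted p 0.861). With the planned 12 separate arrays these 2 calls were lost at means of 0.27 and -0.062 (adjusted p 0.122 and 0.0921, and 0.104 and 0.101 with the replicate block). Among members with a high signal, Lck, a T cell kinase, differed by 0.44 ± 0.23 and Actc1, cardiac actin, by 0.73 ± 0.35. The other 26 lists had means from -0.34 (adipose and mesothelium) to 0.093 (smooth muscle) and a smallest adjusted p of 0.0752. Adjusted over the list alone, 4 members in 3 lists passed.

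T/HS-LDL was compared with T/SS-LDL to find transcripts that differ with shock in the absence of lung injury. Il1b was higher in T/HS-LDL by 2.21 ± 0.38 (SE, n = 2 samples per group, limma adjusted p 0.998). Il1r2, a decoy receptor for interleukin 1, was higher by 1.56 ± 0.31 and Fgr, a kinase of myeloid cells, by 0.57 ± 0.12 (limma adjusted p 0.998 for both). All 13 neutrophil genes were higher, with a mean of 0.74 ± 0.17 (camera adjusted p 3.64e-10, 0.260 with estimated correlation). Of them, 9 did not overlap between groups. The chance is 16.7% for 1 gene, and genes that vary together are not independent trials. The neutrophil call was kept with each sample left out, with means from 0.66 to 0.82 and adjusted p up to 1.25e-05.

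Cryab (-0.53 ± 0.11), Tmem47, a junction protein (-0.70 ± 0.14), Klkb1, plasma kallikrein (-0.97 ± 0.20), Akap5, a scaffold for kinases (-0.52 ± 0.09), St3gal5, which makes gangliosides (-0.50 ± 0.10), Ift25, a protein of cilia (-0.64 ± 0.13), and Cyp2f4, a cytochrome P450 of club cells (-0.52 ± 0.11), were lower in both T/HS-LDL samples, each with a limma adjusted p of 0.998. Klkb1, Ift25 and Cyp2f4 were also higher in T/SS-LDL than in T/SS. That comparison shares the T/SS-LDL samples with opposite sign, so these are not separate findings. The same holds for the lists of the mitochondrial respiratory chain and of smooth muscle below. Limma called 0 probe sets, with 331 at an unadjusted p under 0.05, fewer than the 437 expected by chance, and 66 under 0.01 (29 higher, 37 lower). With the 12 arrays as separate samples 127 passed, 47 with the replicate block and 0 with the sample as a random block; the simulated median for separate arrays was 294. No probe set passed with any sample left out.

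Smooth muscle and pericyte genes were lower in 9 of 9 genes, with a mean of -0.48 ± 0.07 (camera adjusted p 2.62e-08, 0.611 with estimated correlation). Myl9, a myosin light chain of smooth muscle, differed by -0.76 ± 0.20 and Acta2, smooth muscle actin, by -0.37 ± 0.21. This call was kept with each sample left out, with means from -0.64 to -0.32 and adjusted p up to 0.00214. Heart muscle genes had a mean of -0.47 ± 0.14 (adjusted p 0.000954, 0.617 with estimated correlation), with Actc1 at -1.28 ± 0.35, and the call was lost at a mean of -0.44 without T/SS-LDL replicate 2 (adjusted p 0.0621) and of -0.071 without T/HS-LDL replicate 2 (adjusted p 0.672). Airway club and ciliated cell genes had a mean of -0.22 ± 0.09 (adjusted p 0.00493, 0.421 with estimated correlation, 0.0116 by fry), with Aldh1a1, an aldehyde dehydrogenase, at -0.53 ± 0.18; without T/SS-LDL replicate 2 the mean stayed at -0.23 and the adjusted p was 0.0621. The mitochondrial respiratory chain had a mean of -0.15 ± 0.05 (adjusted p 0.00493), immediate early genes one of 0.14 ± 0.06 (adjusted p 0.0299) and NF-kB targets one of 0.33 ± 0.17 (adjusted p 0.0309), with adjusted p of 0.617, 0.611 and 0.617 with estimated correlation. The first call was lost without the averaged T/SS-LDL sample (mean -0.080, adjusted p 0.527) or the averaged T/HS-LDL sample (-0.026, 0.769), and the second without the averaged T/SS-LDL sample (0.064, 0.404) or T/HS-LDL replicate 2 (0.068, 0.326). The NF-kB call was lost at a mean of 0.33 without the averaged T/SS-LDL sample (adjusted p 0.266) or T/SS-LDL replicate 2 (adjusted p 0.0687), and at a mean of 0.019 without T/HS-LDL replicate 2 (adjusted p 0.828). The NF-kB score was 0.68 in T/HS-LDL replicate 2 and 0.76 in T/HS replicate 2, against -0.05 to 0.05 in the other samples, and these were the samples with the highest mean 3' minus 5' difference of control transcripts (0.963 and 0.946, against at most 0.876). With the planned 12 separate arrays the calls of NF-kB targets (0.23, adjusted p 0.248), heart muscle genes (-0.33, adjusted p 0.0990) and immediate early genes (0.14, adjusted p 0.0609) were lost, the first also with the replicate block (adjusted p 0.213). The other 26 lists had means from -0.21 (adipose and mesothelium) to 0.25 (monocytes and macrophages) and a smallest adjusted p of 0.127. Adjusted over the list alone, 8 members in 6 lists passed, 3 of them neutrophil genes.

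T/SS-LDL was compared with T/SS to measure the effect of ligation without shock. Pkia, an inhibitor of protein kinase A, was higher in T/SS-LDL by 0.79 ± 0.14 (SE, n = 2 samples per group, limma adjusted p 0.896). Cyp2f4 was higher by 0.53 ± 0.11, Me1, malic enzyme, by 0.66 ± 0.14, Sqle, an enzyme of sterol synthesis, by 0.54 ± 0.13, Klkb1 by 0.84 ± 0.20, Ift25 by 0.60 ± 0.13 and Prnp, the prion protein, by 0.45 ± 0.11, each with a limma adjusted p of 0.896. T/HS-LDL against T/SS-LDL uses the same T/SS-LDL samples with opposite sign. High T/SS-LDL values of Cyp2f4, Klkb1 and Ift25 thus enter both comparisons. Fabp1, a fatty acid carrier (-0.42 ± 0.09), Anapc13, a subunit of a mitotic ubiquitin ligase (-0.54 ± 0.13), and Dlx5, a homeobox gene (-0.43 ± 0.11), were lower with the same adjusted p. Limma called 0 probe sets, with 370 at an unadjusted p under 0.05 and 55 under 0.01 (25 higher, 30 lower). With the 12 arrays as separate samples 141 passed, 21 with the replicate block and 0 with the sample as a random block. The simulated median for separate arrays was 297, above the real count, and does not measure false calls for these arrays. Counts with a sample left out rest on a lone sample in that group, whose spread is taken from the other groups. Without the averaged T/SS sample 1 passed, and without T/SS-LDL replicate 2, 2 passed.

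Mitochondrial respiratory chain genes were higher in T/SS-LDL in 25 of 25 genes, by a mean of 0.13 ± 0.02 (camera adjusted p 0.00236, 0.612 with estimated correlation), a call lost without the averaged T/SS-LDL sample (mean 0.065, adjusted p 0.193). Neutrophil genes were higher by 0.38 ± 0.13 in 9 of 13 genes (adjusted p 0.0248, 0.457 with estimated correlation), with S100a9 higher by 0.87 ± 0.39; the call was lost without T/SS replicate 1 (mean 0.26, adjusted p 0.159) or T/SS-LDL replicate 2 (mean 0.34, adjusted p 0.255). Smooth muscle genes were higher by 0.21 ± 0.06 (adjusted p 0.0353, 0.706 with estimated correlation), lost without the same samples (means 0.014 and 0.053, adjusted p 0.946 and 0.716). Mast cell genes were lower in 11 of 12 genes, with a mean of -0.16 ± 0.05 (adjusted p 0.0353, 0.457 with estimated correlation), lost without the averaged T/SS sample (mean -0.13, adjusted p 0.114) or the averaged T/SS-LDL sample (mean -0.077, adjusted p 0.380), and Tpsb2, a mast cell tryptase, differed by -0.29 ± 0.14. The mast cell call was also lost with the mean of a gene's probe sets (-0.13, adjusted p 0.0975). Of the 12 measured mast cell genes, 1 lay above the median gene in T/SS, so this list rests mostly on dim signal. With the planned 12 separate arrays the neutrophil and smooth muscle calls were lost at means of 0.33 and 0.092 (adjusted p 0.123 and 0.383, and 0.0870 and 0.418 with the replicate block). The other 29 lists had means from -0.11 (immediate early genes) to 0.38 (adipose and mesothelium) and a smallest adjusted p of 0.0791. Adjusted over the list alone, 2 members in 2 lists passed.

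**Figure D3:**
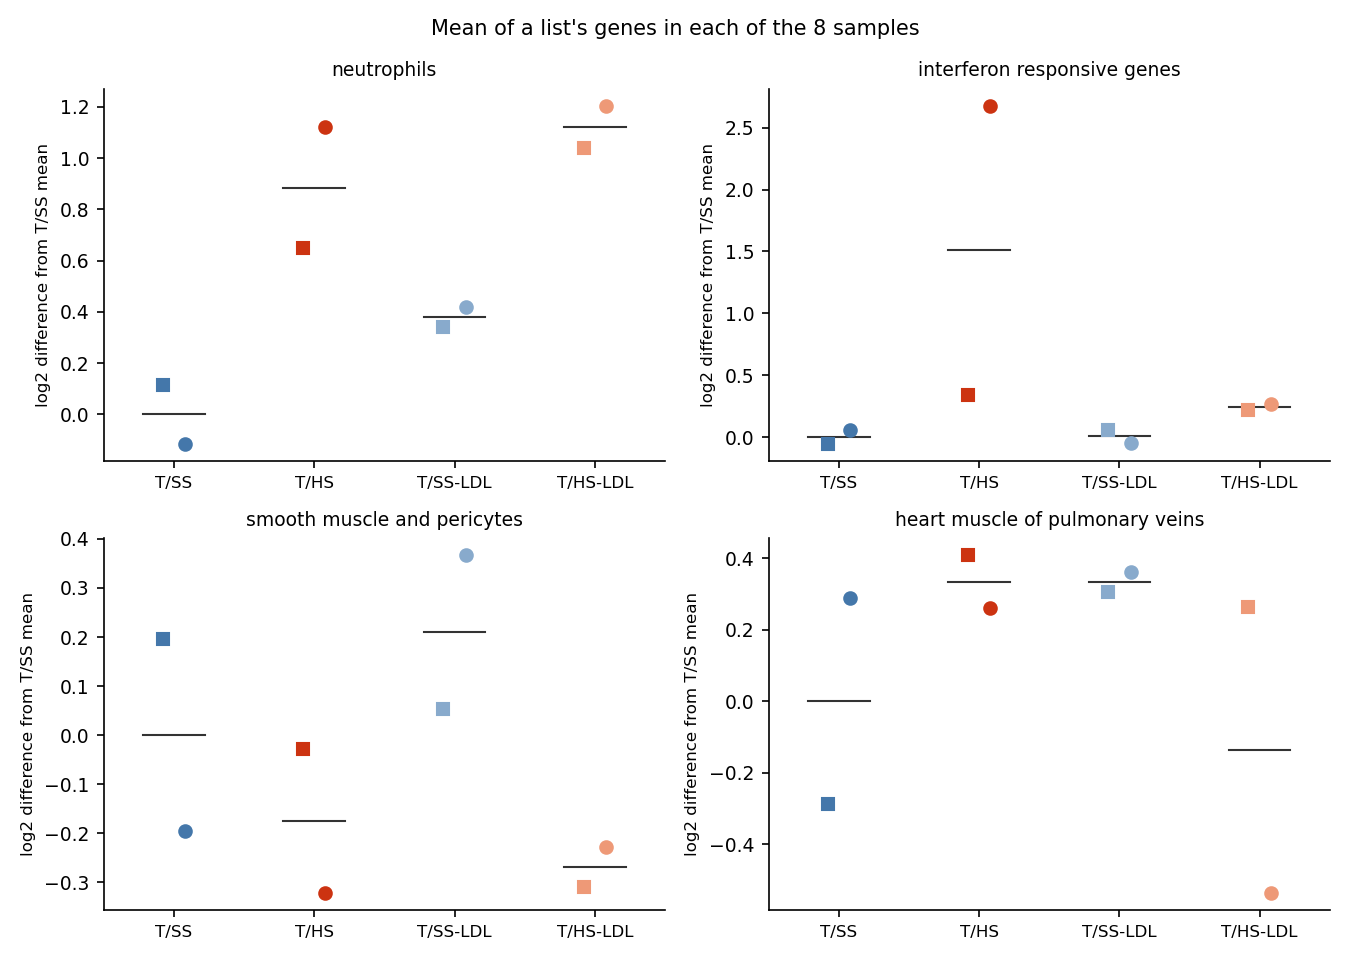
Mean log2 difference from the T/SS mean (y axis) of the genes of 4 lists in each of the 8 samples, by group, with squares for averaged pairs of arrays, circles for single arrays and a line at the group mean. Neutrophil scores were 0.65 to 1.20 in shocked and -0.12 to 0.42 in sham-shocked samples, and the interferon score of 2.68 came from 1 T/HS sample.

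The interaction asks whether the shock effect differed without and with ligation. Mapk12 had the smallest p, with an interaction of -0.93 ± 0.16 on the log2 scale, and was followed among others by Canx (-1.13 ± 0.25), Cyb5a (-1.18 ± 0.27), Irgq, a GTPase-like protein (-0.91 ± 0.20), Zfp706 (-0.88 ± 0.20), Sult2a6 (-0.78 ± 0.16), Abcc3 (-0.72 ± 0.18), Marchf8 (-0.69 ± 0.18), C8h15orf61 (-0.58 ± 0.13) and Lpl (-1.45 ± 0.37), none of which passed. Limma called 0 probe sets, with 261 at an unadjusted p under 0.05 and 40 under 0.01 (12 higher, 28 lower). With the 12 arrays as separate samples 1 passed, 1 with the replicate block and 0 with the sample as a random block. The simulated median for separate arrays was 314.5. Counts with a T/HS sample left out rest on a lone T/HS sample, whose spread is taken from the other groups. Without the averaged T/HS sample 27 passed, all higher, and without T/HS replicate 2, 1 passed.

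By camera's test of the interaction, heart muscle genes differed by 0.81 ± 0.22 (14 of 17 genes higher, adjusted p 1.11e-05) and interferon responsive genes by 1.27 ± 0.22 (15 of 17, adjusted p 1.94e-05). Heat shock genes differed by -0.33 ± 0.09 and mast cell genes by -0.27 ± 0.09 (adjusted p 0.00505 for both), and smooth muscle genes by 0.30 ± 0.09 (adjusted p 0.0144). With estimated correlation the adjusted p was 0.618 for all 5. Of the 12 measured mast cell genes, 1 lay above the median gene in T/SS. With each sample left out in turn the heart muscle mean lay between 0.41 and 1.21. Heart muscle scores spread widely within groups, at 0.29 and -0.29 in T/SS and 0.26 and -0.54 in T/HS-LDL. The SE of this interaction is over genes and does not measure that spread over samples. Without T/HS replicate 2 the interferon interaction was 0.10 with an adjusted p of 0.743. The heat shock call was lost without the averaged sample of T/HS, T/SS-LDL or T/HS-LDL, with means of -0.31, -0.23 and -0.11 (adjusted p 0.114, 0.208 and 0.706), and the mast cell call without the averaged T/SS-LDL sample, with a mean of -0.18 (adjusted p 0.208). The smooth muscle call was lost without T/SS replicate 1 (0.11), T/SS-LDL replicate 2 (0.15), the averaged T/HS sample (0.16) or the averaged T/HS-LDL sample (0.26), with adjusted p of 0.251 to 0.665, and with the planned 12 separate arrays (0.25, adjusted p 0.118, and 0.143 with the replicate block). Neutrophil genes had an interaction of 0.14 with an adjusted p of 0.517. The other 28 lists had means from -0.16 (oxidative stress) to 0.39 (cytokines and chemokines) and a smallest adjusted p of 0.0541. Adjusted over the list alone, 1 member passed.

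Fold changes were compared across 4736 genes, which are not independent replicates, for 3 pairs of comparisons. Both shock comparisons, which share no arrays, had Pearson's r of 0.403 and Spearman's rho of 0.282. In 200 simulations of unchanged groups, r was -0.216 to 0.206. The simulations for all 3 pairs drew genes independently. Genes that vary together would widen this range and raise the numbers of shared calls expected below. Neither r nor the shared calls are thus shown to lie beyond chance. Il1b (2.90 and 2.21), Il1r2 (1.59 and 1.56), Ceacam4, an adhesion molecule of granulocytes (1.65 and 1.58), Alox5ap, which serves leukotriene synthesis (0.65 and 0.57), Pglyrp1, a peptidoglycan-binding protein of neutrophils (0.61 and 0.62), and Fgr (0.47 and 0.57) were higher at an unadjusted p under 0.01 in both, 6 genes against 0.136 for independent calls. Cryab (-0.61 and -0.53), Kank2, a cytoskeletal protein (-0.84 and -0.58), and Tmem47 (-0.65 and -0.70) were lower in both, 3 genes against 0.293. Of these, Ceacam4 and Pglyrp1 fall outside the naming rule and were chosen after their values were seen. The jackknife SE of r over samples was 0.134, and without T/HS replicate 2, r was 0.247.

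T/HS against T/SS and T/HS against T/HS-LDL, which share the T/HS samples, had r of 0.693 and rho of 0.608, against 0.343 to 0.602 for r in simulations of unchanged groups. The jackknife SE of this r over samples was 0.212, more than its distance from that range, and with 1 sample left out r lay between 0.571 (without T/HS-LDL replicate 2) and 0.860 (without the averaged T/HS sample), so it is not shown to lie beyond the range. In both, 28 genes were lower at an unadjusted p under 0.01 (0.652 for independent calls, which shared samples raise) and 1, Neurl3, a ubiquitin ligase chosen after its values were seen, was higher. T/HS against T/HS-LDL and T/HS-LDL against T/SS-LDL had r of -0.058 and rho of -0.042, against -0.609 to -0.384 in the simulations. With a jackknife SE of 0.411, this r was not shown to differ from the simulated values: it was -0.369 without the averaged T/HS-LDL sample, -0.322 without T/HS-LDL replicate 2, -0.215 without T/HS replicate 2, -0.181 without the averaged T/SS-LDL sample, 0.089 without T/SS-LDL replicate 2 and 0.101 without the averaged T/HS sample.

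**Figure D4:**
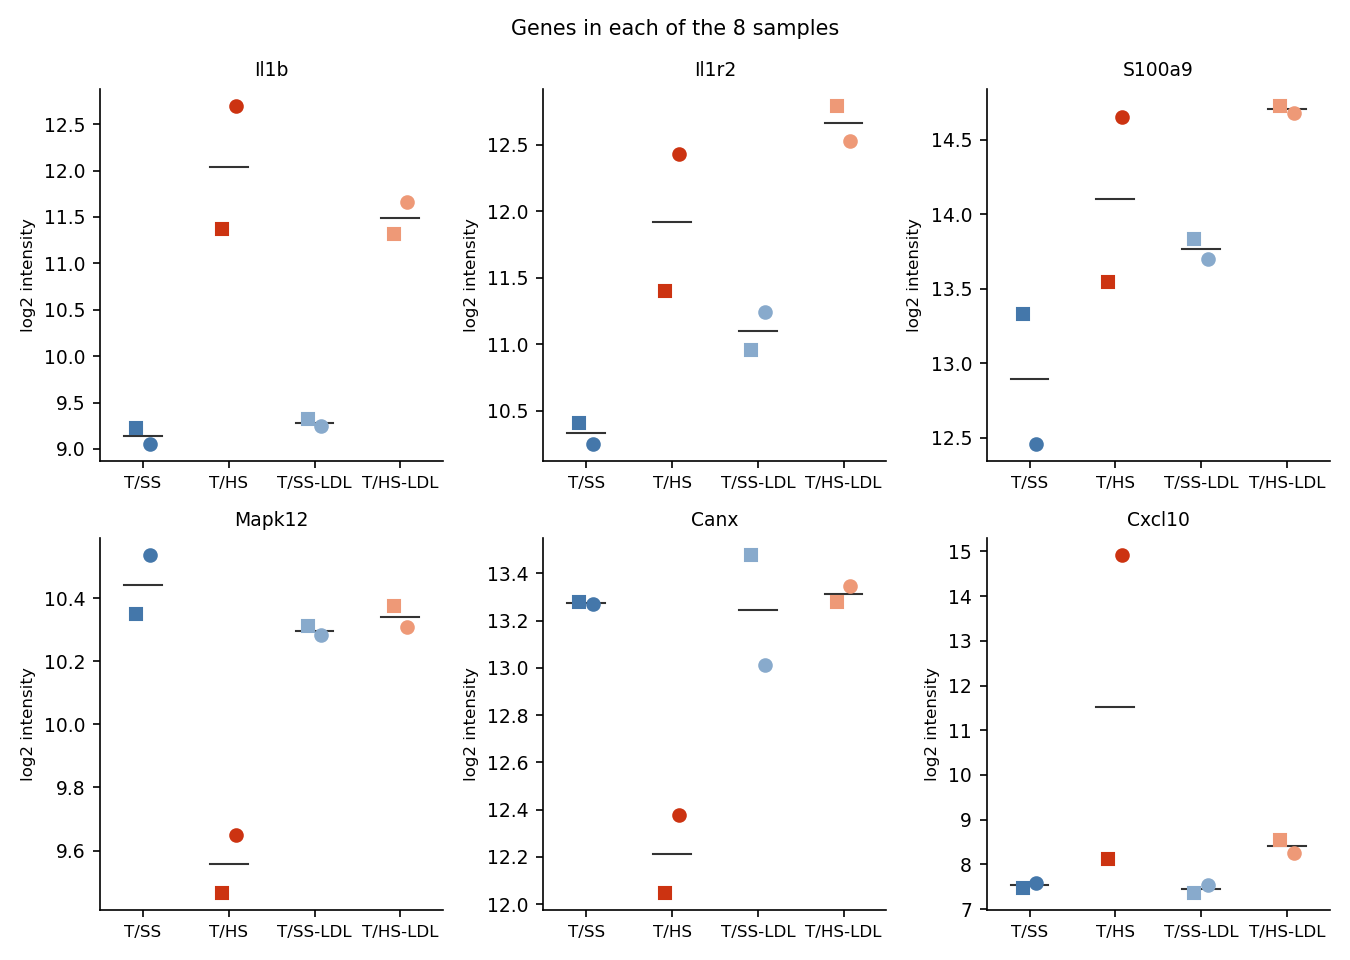
Log2 intensity (y axis) of 6 genes in each of the 8 samples, by group, with squares for averaged pairs of arrays, circles for single arrays and a line at the group mean. Il1b was higher in shocked groups with and without ligation (2.90 and 2.21), Mapk12 and Canx were lower in T/HS than in T/SS (-0.89 and -1.06), and Cxcl10 differed mostly in 1 T/HS sample.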

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

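Tests in this part were chosen after the results they concern had been seen, except the interaction tests, which had been planned for 12 separate arrays; the counts over other splits were set out before those counts were seen, but for 8 samples and a comparison, shock over both ligation states, chosen after the data were seen. The shock effect differed with ligation, by camera's test of the interaction, for heart muscle genes (0.81), interferon responsive genes (1.27), heat shock and protein folding genes (-0.33), mast cell genes (-0.27) and smooth muscle and pericyte genes (0.30), and each is given here for that reason. With estimated correlation none of the 5 passed (adjusted p 0.618). The heart muscle scores of the samples were -0.29 and 0.29 in T/SS, 0.26 and 0.41 in T/HS, 0.30 and 0.36 in T/SS-LDL, and -0.54 and 0.26 in T/HS-LDL.

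Near-identical arrays occur once in every group. The pairs were chosen by their low robust SD, but a choice of the lowest pairs does not by itself leave a gap below the rest. Separate rats on separate arrays are argued against by that gap: the highest robust SD in such a pair was 0.0548, against a lowest of 0.164 in the other 62 pairs, whose SD over pairs was 0.031. Repeated measurement of 1 labelled RNA needs the spike-ins, added to each labelled RNA, to differ least in these pairs, and their highest RMS log2 difference was 0.0541, against a lowest of 0.106 in the other pairs of a group. It may therefore be the source, although a pair from different groups came as low as 0.05, so a single pair does not settle it. A file copied with small changes was not tested, and no biological explanation was tested.

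Interferon responsive genes were high in T/HS replicate 2, with a score of 2.68. RNA quality stays open. The 3' minus 5' difference of this sample, as a mean over 3 control transcripts, was 0.946, within the range of the other samples but near its top. It was 0.963 in T/HS-LDL replicate 2, whose interferon score was 0.27, so 1 sample had such a difference without a high score. It was at most 0.876 in the others. For hexokinase alone, T/HS replicate 2 was the highest of the 8 samples, at 1.49. T and NK cells are argued against by their score of 0.035 in this sample, and of -0.034 over the 6 of their 20 genes above the median gene. An effect of shock, an infection of this rat, or a response to shock that varies between rats may underlie the pattern, and none of these was tested.

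Shocked samples differed from sham-shocked samples in neutrophil genes, by 0.81 ± 0.20 (SE over 13 genes) over both ligation states. More blood of unchanged makeup, or more leukocytes of every kind, would raise the genes of other blood cells as well; the least such rise was set at 0.41, against the neutrophil shift of 0.81, after the values were seen, and no value measures it. A rise of 0.41 from more blood is argued against by the 8 erythroid and platelet genes below the ceiling, which differed by -0.13 ± 0.06 (SE over samples 0.15). The 5 of them above the median gene differed by -0.21 ± 0.09 (SE over samples 0.20). Over samples the first value is within 1 SE of no change, so a small rise from more blood stays open. The 20 T and NK cell genes differed by 0.11 ± 0.07 (SE over samples 0.12), with scores from -0.22 to 0.42 in shocked samples, the highest in the averaged T/HS sample. A rise of 0.41 in T and NK cell genes is argued against by the 6 of these genes above the median gene. They differed by -0.0093 ± 0.026 (SE over samples 0.079), with scores up to 0.17 in shocked samples. Monocyte and macrophage genes were higher with shock by 0.23, with scores of 0.07 to 0.34 in shocked and -0.04 to 0.06 in sham-shocked samples. A smaller rise of leukocytes of every kind therefore stays open. Chance cannot be excluded for the numbers of calls. In a fit of 2 groups that leaves ligation out, and so differs from the fit behind the 220 probe sets and 9 lists of shock over both ligation states, 3 of the 35 splits of the 8 samples gave at least as many probe sets at an unadjusted p under 0.01 (185 in the real split, 260 in the highest other), and 3 of 35 gave at least as many lists (10 in the real split, 12 in the highest other). An effect of shock on neutrophils in the lung may underlie the neutrophil list. Its camera p in the real split (9.07e-12) was the smallest of the 35, but another split came nearly as low (1.13e-11). The list was also singled out from these same samples, so this rank is no support for such an effect.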

How the results depend on the processing

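The fit to 8 samples was chosen after the data were seen, in place of the planned 12 separate arrays and their planned replicate block, which are given here as alternatives to it; the random block, every result on shock over both ligation states, and lists without Il1b or Cxcl10 were also chosen then, and the other alternatives were planned. Limma's counts of 0 probe sets past an adjusted p of 0.05 stayed 0 with common medians, quantile normalization, probe sets above the median value, gene means, trend and robust, an offset of 16 and an adjusted p of 0.10, with the compared groups alone in the 4 comparisons of a pair of groups, and with array weights except for 2 in shock over both ligation states; a 1.5-fold minimum cannot change a count of 0. In the order T/HS against T/SS, T/HS against T/HS-LDL, T/HS-LDL against T/SS-LDL, T/SS-LDL against T/SS, interaction, and shock over both, the counts were 629, 372, 127, 141, 1 and 733 with 12 separate arrays, 456, 130, 47, 21, 1 and 570 with the replicate block, 25, 0, 0, 0, 0 and 58 with the sample as a random block, and 200, 106, 66, 55, 40 and 220 at an unadjusted p under 0.01. Treating near-identical arrays as replicates lowers the spread by construction. With 1 sample left out, where a lone sample is assumed to vary like the others, counts ranged from 0 to 139, 0 to 66, 0 to 0, 0 to 2, 0 to 27 and 0 to 108; each highest count above 0 came without the averaged T/HS sample (without T/SS-LDL replicate 2 for T/SS-LDL against T/SS, which had 1 without the averaged T/SS sample), and without T/HS replicate 2 the counts were 5 for T/HS against T/SS, 4 for T/HS against T/HS-LDL, 1 for the interaction and 10 for shock over both. Camera's 6, 7, 7, 4, 5 and 9 called lists became 0 throughout with estimated correlation and 0, 0, 1, 0, 0 and 2 with fry. Over 12 separate arrays 4 lists passed for T/HS-LDL against T/SS-LDL, 2 for T/SS-LDL against T/SS and 5 for shock over both, also 5 there with the replicate block. With 1 sample left out, called lists ranged from 5 to 8, 4 to 8, 4 to 7, 2 to 4, 3 to 10 and 5 to 11. They were fewest without the averaged T/HS-LDL sample for T/HS against T/HS-LDL (4) and the interaction (3, and also 3 without the averaged T/SS-LDL sample), and without T/SS-LDL replicate 2 for T/HS-LDL against T/SS-LDL (4), T/SS-LDL against T/SS (2, and also 2 without the averaged T/SS-LDL sample) and shock over both (5, and also 5 without T/HS-LDL replicate 2). The interaction had 10 without T/HS-LDL replicate 2 and 8 without either T/HS sample. Of the 38 called lists, 37 passed with the mean of a gene's probe sets (mast cells in T/SS-LDL against T/SS did not), 24 with 12 separate arrays, 26 with the replicate block, 3 with fry and 0 with estimated correlation, and all 4 lists tried without Il1b and all 4 without Cxcl10 still passed. Camera's direction for NF-kB targets in T/HS-LDL against T/SS-LDL reversed without T/HS-LDL replicate 2, where the mean was 0.019 with an adjusted p of 0.828; over the samples left out the mean ranged from 0.019 to 0.64. Pearson's r between both shock comparisons was 0.247 without T/HS replicate 2 and at most 0.400 with another sample left out. With estimated correlation, camera also rests on the 4 residual degrees of freedom, so a lost call need not reflect correlation between genes. For acute phase genes in T/HS against T/SS the estimate was -0.0073, below the preset 0.01. Camera's unadjusted p still rose from 0.00181 to 0.0279. How much each of these contributes was not tested. For fry and the samples left out, the cause was not tested either. Of the 60 named gene results from the smallest p-values, whose direction was largely fixed by that choice, 50 passed with 12 separate arrays, 45 with the replicate block, 14 with the random block and 1 with array weights. Of the 60, 45 lay above the median value, and 0 passed in the fit to such probe sets alone. How far dim signal limits these results was not tested.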

Other observations

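Shock over both ligation states (4 shocked against 4 sham-shocked samples) and its tests were chosen after the data were seen. Il1b was higher with shock by 2.55 ± 0.27 on the log2 scale (limma adjusted p 0.156), Il1r2 by 1.58 ± 0.22, Ccr2 by 0.48 ± 0.07, Alox5ap by 0.61 ± 0.10 and Fgr by 0.52 ± 0.09, while Cryab differed by -0.57 ± 0.08, Tmem47 by -0.67 ± 0.10, Kank2 by -0.71 ± 0.11, Ndufc1 by -0.64 ± 0.10 and Akap5 by -0.39 ± 0.07. Limma called 0 probe sets at an adjusted p of 0.05 (smallest 0.142, for a probe set with no gene symbol), with 790 at an unadjusted p under 0.05 and 220 under 0.01 (95 higher, 125 lower), and 2 with array weights. Counts with a T/HS sample left out rest on a lone T/HS sample, whose spread is taken from the other groups. Without the averaged T/HS sample 108 passed, and without T/HS replicate 2, 10 passed.

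Neutrophil genes were higher with shock by a mean of 0.81 (13 of 13 genes, camera adjusted p 4.26e-11, 0.223 with estimated correlation, 0.0277 by fry). Camera also called interferon responsive genes (0.87), smooth muscle genes (-0.33), the mitochondrial respiratory chain (-0.13), acute phase genes (0.23), NF-kB targets (0.36), airway genes (-0.19; 0.0143 by fry), cytokines (0.34) and monocytes and macrophages (0.23), with adjusted p of 0.406 to 0.542 with estimated correlation. Neutrophil, interferon and smooth muscle calls were kept with each sample left out (adjusted p up to 7.91e-09, 0.000313 and 0.00758), although the interferon mean was 0.29 without T/HS replicate 2. Without T/HS replicate 2 the calls of cytokines (0.15), acute phase genes (0.15), NF-kB targets (0.18) and monocytes and macrophages (0.16) were lost. They were also lost without T/HS-LDL replicate 2 (0.32, 0.21, 0.21 and 0.24), without T/SS-LDL replicate 2 except for NF-kB targets (0.32, 0.16 and 0.22), and for monocytes and macrophages without T/SS replicate 1 (0.21). The mitochondrial call was lost without the averaged T/HS-LDL sample (-0.070) or that of T/SS-LDL (-0.097), and the airway call without T/SS-LDL replicate 2, at a mean of -0.19 (adjusted p 0.0625). With 12 separate arrays the calls of acute phase genes (0.17), cytokines (0.26), NF-kB targets (0.26) and monocytes and macrophages (0.20) were lost, with adjusted p of 0.0841 to 0.240, and of 0.0819 to 0.230 with the replicate block. In a two-sided exact permutation test of the scores of 4 against 4 samples, 7 lists reached p 0.0286, the smallest such a test can give, with a Benjamini-Hochberg adjusted p of 0.135: neutrophils, interferon responsive genes, cytokines, monocytes and macrophages, airway genes, glucocorticoid responsive genes and vascular tone. Adjusted over the list alone, 31 members in 13 lists passed, 9 of them neutrophil genes. Of the 13 measured neutrophil genes, 5 were also on other lists and 6 lay above the median gene in T/SS; of the 17 interferon genes, 2 and 12.

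Adipose and mesothelium genes had a score of 0.73 in the averaged T/SS-LDL sample and -0.21 to 0.30 in the other samples. Heart muscle genes had a score of -0.54 in T/HS-LDL replicate 2. The mean spike-in signal of T/SS-LDL replicate 2 lay -0.95 from the median of the samples on the log2 scale. The 3' minus 5' differences of control transcripts had an exact permutation p of at least 0.143 over both ligation states; in the comparisons of 2 against 2 samples the smallest possible p was 0.333, reached by several, so these tests could not pass and leave a difference in RNA quality between groups open. As a mean over the 3 transcripts the difference was highest in T/HS-LDL replicate 2 (0.963) and T/HS replicate 2 (0.946), the samples that alone had high NF-kB scores (0.68 and 0.76), and RNA quality stays open for the NF-kB calls.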
